A study of Mus musculus with 11 samples.

How the data were processed

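RNA of sorted Tregs was measured in 11 libraries from 7 mice, taken on day 7 after intravaginal HSV-2 or a mock inoculation. Per the labels' protocols, cells went directly into lysis buffer of the SMART-seq v4 kit, which makes full-length cDNA amplified by PCR, and libraries were made with Nextera XT and read as single 58-base reads on a HiSeq 2500 with a target of 5000000 reads. Other parts of the labels speak of a 3' transcriptome, and the 2 descriptions were not reconciled here. Neither kit marks the strand of origin, so reads of overlapping antisense genes cannot be told apart. The chemistry has no molecular identifiers, and intervals and bounds on counts therefore cover counting error only.

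The deposited table holds expected counts per gene, as estimated by a probabilistic assignment of reads, in 12317 rows; 28.5% of its entries are not whole numbers. Per the submitters' processing notes, STAR 2.4.2a and RSEM 1.2.22 were used with the mm10 and GRCm38 builds, and edgeR and limma are named. The labels' extraction protocol names htseq-count as the counter, and the fractional values do not come from plain htseq-count counting. An expected count can divide reads among near-identical genes, so members of families such as the guanylate-binding proteins, the interferon-inducible GTPases, Hspa1a and Hspa1b, and the class I genes are uncertain individually. In the table, 17 row names had been turned into dates and 5 names occurred more than once; these rows were kept in totals and not named. Of the row names, 91.7% matched a gene of GENCODE M21 (GRCm38) or RefSeq, from which positions were taken. Genes on the fixed lists that had no row are counted as not analysed here, among them every fibroblast and erythroid marker.

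Expected counts were rounded to whole numbers. Each comparison used only the libraries of its 2 groups: infected against mock lymph node (4 against 3), infected tissue against infected lymph node (4 against 4) and infected tissue against mock lymph node (4 against 3). Genes were kept by edgeR's filterByExpr with its defaults (a minimum count of 10 and total of 15), libraries were scaled by TMM, and differences were tested with edgeR 4.0.16 (quasi-likelihood F test, robust) in R 4.3.3. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Standard errors are the log2 fold change divided by the square root of F. Levels are CPM as edgeR computes them, from counts divided by the TMM-scaled library total. Medians of log2 fold change over all genes were 0.00, -0.02 and -0.05 in the 3 comparisons. Where a group had 0 counts of a gene, its fold was computed against 3 counts over the group. Such a fold bounds counting error and leaves out the spread between mice. With 1 to 3 counts the ratio is given with an exact 95% Poisson interval.

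Before the data were examined, 16 gene lists of Treg and T cell biology and 9 lists of markers of other cell types were fixed, along with the alternatives and the rule for named genes. The rule took Foxp3, Cd4, Il2ra, Ctla4 and Ikzf2, the 8 higher and 8 lower called genes with the largest fold, no overlap of libraries and a mean of at least 20 CPM in the higher group (5 and 5 in the third comparison), up to 3 called members of each biology list, and the marker with the highest mean per other cell type. Unnamed gene models, ribosomal protein, mitochondrial, immunoglobulin and T cell receptor genes and other-cell-type markers were left out of the genes chosen by fold. Lists with at least 4 tested genes were tested with camera (limma 3.58.1, preset correlation 0.01), with camera's estimated correlation, and with fry, whose directional p asks whether a list's genes move on balance one way and whose mixed p whether they change either way. In the first comparison the calls of 4 of 14 lists held with an estimated correlation (interferon-stimulated, class I, activation and Th1-type), in the second 0 of 11 and in the third 8 of 14. Library measures were compared by exact two-sided permutation tests. These cannot give a p below 0.057 with 3 against 4 libraries or below 0.029 with 4 against 4.

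Tissue and lymph node libraries of infected mice share animals per the labels' mouse letters, which pairs them. Deviations of the 2 libraries of a mouse from their group means correlated by -0.0005, 0.025, 0.084 and -0.010 in mice d to g (mean 0.025), and by -0.0069 on average between different mice. The main test had no block, and a fit with mouse as a block was an alternative. Both libraries of mouse g carry a later series of library numbers in the table's column names than the other 9, so a batch is possible; no mock library has a later number. Without a block, p-values measure the spread between mice within a group, and the paired libraries were taken as independent. With mouse as a block, they measure the spread between mice of the difference between tissue and lymph node.

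On simulated counts with the means, library totals and spread of each comparison and 200 genes changed, the test recovered 15% of 2-fold and 44% of 4-fold changes among 10781 genes of the first comparison, 14% and 35% among 10424 genes of the second and 4% and 29% among 10586 genes of the third, with 2, 2 and 1 false calls. Alternatives were other scalings, filters, tests (DESeq2 1.42.0, limma-voom with and without quality weights), all 11 libraries in 1 fit, thinning to equal totals, a 2-fold minimum and leaving out each library. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.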

Results

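FoxP3-positive regulatory T cells (Tregs), CD4 T cells that restrain immune responses, were sequenced from mice in which green fluorescent protein reports the Treg transcription factor FoxP3. All mice had received medroxyprogesterone acetate, a progestin given before intravaginal herpes simplex virus type 2 (HSV-2) because it makes the vaginal epithelium permissive. Live CD45+ CD4+ FoxP3+ cells were sorted on day 7 after HSV-2 or after a mock inoculation with buffer. The 11 libraries fell into 3 groups: draining lymph node of mock mice (3 mice, named a to c), draining lymph node of infected mice (4 mice, d to g) and vaginal tissue of the same infected mice (4 libraries, mice d to g). Tissue cells were in addition gated as negative for a CD45.2 antibody given intravenously, which marks cells inside blood vessels. The estimated counts assigned to genes summed to between 3844075 and 7774093 per library. The design asks how infection changed lymph node Tregs, and how Tregs in the infected tissue differed from those of the node that drains it. No mock tissue was analysed here, so tissue and infection cannot be separated in the comparison of infected tissue with the mock node.

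Totals averaged 5790339 ± 1717228 counts in mock nodes (SD, n = 3), 6835414 ± 889592 in infected nodes (n = 4) and 5969062 ± 1037857 in tissue (n = 4). Infected lymph node libraries resembled each other most, with a mean correlation of log2 CPM with their own group of 0.885 ± 0.00964, against 0.804 ± 0.00626 in mock nodes and 0.822 ± 0.0288 in tissue. The tissue library of mouse d stood apart. At equal totals it held counts for 9392 genes, while the other 3 tissue libraries held counts for 10910 to 11303, and 18.3% of the genes that passed the expression filter were at 0 in it. No pair of libraries within a group agreed within sampling noise (chi-square per degree of freedom of at least 21.6).

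**Figure D1:**
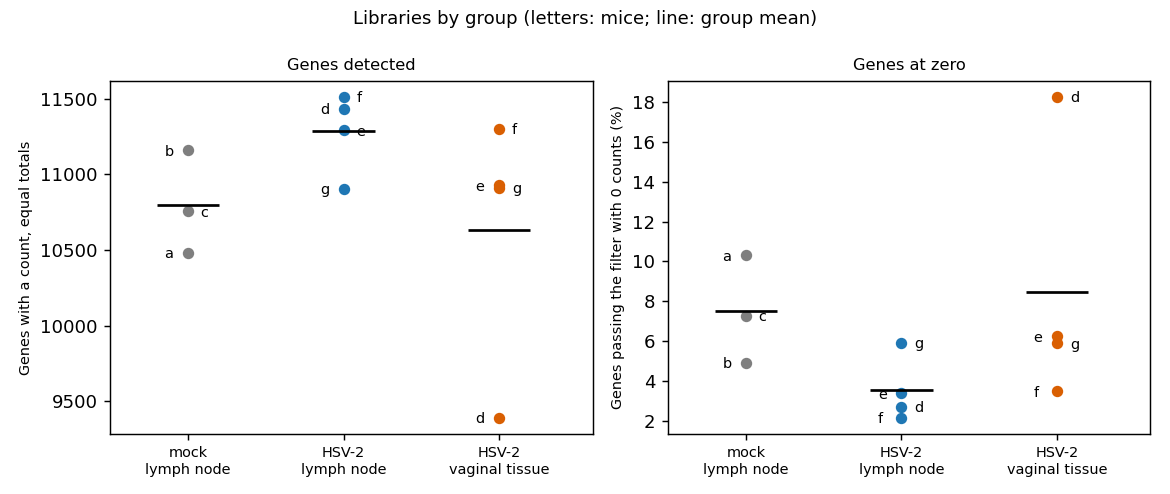
Genes with at least 1 count after every library was thinned to the same total (left) and percent of genes passing the expression filter that had 0 counts (right), with 1 point per library, labelled with its mouse, and a line at each group mean. The tissue library of mouse d lies lowest on the left, at 9392 genes, and highest on the right, at 18.3%.

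Infection in the lymph node was accompanied by a rise of interferon-stimulated genes, of Treg activation genes and of class I antigen presentation genes. Of the genes of lymphoid recirculation, 4 of 23 fell, and that list lost its call with an estimated correlation (adjusted p = 0.13). Ly6a, which encodes the surface protein Sca-1 (GRCm38 chromosome 15, 74994877 to 74998031, minus strand), was 6.87-fold higher in infected nodes (2586 ± 535 CPM, SD, n = 4) than in mock nodes (376 ± 42.4 CPM, n = 3). The chemokine receptor gene Ccr7, which guides T cells into and within lymph nodes (chromosome 11, 99144196 to 99155077, minus strand), fell by 1.43 on the log2 scale (SE 0.18, adjusted p = 0.0066), from 1761 ± 417 to 653 ± 112 CPM. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 88 of 10781 tested genes were higher and 57 were lower at an adjusted p under 0.05. Over all tested genes, the libraries of the 2 groups did not overlap in 14.3%, where chance gives 5.71%.

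Of 54 measured interferon-stimulated genes, 22 rose and none fell over all genes tested, and 40 rose when adjusted over the list alone. Their median log2 fold change was 1.13. The list was called by camera (adjusted p = 6.2e-51) and kept its call with an estimated correlation (adjusted p = 0.031 with an estimated correlation). Iigp1, an interferon-inducible GTPase (log2 2.03, SE 0.15, adjusted p = 4.2e-04), reached 468 ± 65.9 CPM against 115 ± 8.25 CPM in mock nodes. Ifi27l2a rose from 658 ± 105 to 2489 ± 417 CPM (log2 1.92, SE 0.16, adjusted p = 7.9e-04) and the guanylate-binding protein gene Gbp2 from 91.6 ± 9.51 to 399 ± 108 CPM (log2 2.12, SE 0.22, adjusted p = 0.0022). Oas2, at 0 counts in the mock group, was 92.1-fold higher when set against 3 counts over the group, a figure that leaves out the spread between mice. Pydc3 (5.51-fold) and Phf11a (4.79-fold), which are on no list, were also among the genes with the largest rise, as were Lamc1, which encodes a laminin chain, and Hspa1a, which encodes an inducible heat shock protein (8.63-fold, from 9.25 ± 3.98 to 79.4 ± 43.6 CPM). Lamc1 and Hspa1a each lost their call in 9 of 17 alternatives, while Pydc3 and Phf11a kept theirs in all 17. Of 16 class I presentation genes, 4 rose (H2-T23, Psme2, Psmb8 and Psmb9) and 13 rose when adjusted over the list alone (adjusted p = 0.031 with an estimated correlation).

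Of 24 Treg activation genes, 5 rose and none fell (10 rose and 1 fell adjusted over the list alone, adjusted p = 0.041 with an estimated correlation). They were the costimulatory receptor gene Icos (2057 ± 268 against 897 ± 107 CPM, 2.29-fold, adjusted p = 0.0034), Tnfrsf9, which encodes 4-1BB (960 ± 293 against 256 ± 23.7 CPM, log2 1.91, SE 0.25, adjusted p = 0.0073), Tnfrsf4, which encodes OX40, the transcription factor gene Batf and the inhibitory receptor gene Tigit. Of 16 Th1-type genes, 2 rose (6 rose and 1 fell adjusted over the list alone), and the list kept its call (adjusted p = 0.044 with an estimated correlation). Cxcr3, a chemokine receptor of Th1-type cells, was 2.92-fold higher (381 ± 36.6 against 131 ± 30.5 CPM). Of 12 Treg identity genes, Tnfrsf18, Il2ra and Il2rb rose (5 rose adjusted over the list alone). Il2ra, the interleukin-2 receptor alpha chain, went from 392 ± 70.7 to 841 ± 172 CPM. The adjusted p of that list was 0.17 with an estimated correlation. Of the genes named as a check of the sort, Cd4 (158 ± 17.0 against 211 ± 42.6 CPM), Ctla4 (1832 ± 234 against 1411 ± 78.7 CPM) and Ikzf2 (635 ± 172 against 643 ± 120 CPM) did not pass the test. The transcript of Foxp3 was not analysed here.

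Of 23 recirculation genes, 4 fell (Ccr7, S1pr1, Klf2 and Tcf7) and none rose (10 fell and 2 rose adjusted over the list alone, adjusted p = 0.13 with an estimated correlation). S1pr1, the receptor by which T cells leave lymph nodes, went from 636 ± 127 to 280 ± 13.4 CPM and the transcription factor gene Klf2 from 461 ± 71.9 to 235 ± 30.7 CPM. The lower genes with the largest folds were Rgcc, a regulator of the cell cycle (442 ± 35.7 CPM in mock nodes, log2 -2.22, SE 0.21, adjusted p = 0.0015), the phosphatase gene Dusp10, Filip1l, Scml4, Cnn3, Rgs16, Ttn and Adh1. Adh1 had 0 counts in the infected group and was 189-fold lower when set against 3 counts over the group, again without the spread between mice. Among 39 immediate-early and stress genes, 5 fell (Dusp1, Ier2, Btg2, Btg1 and Jund) and Hspa1a rose (12 fell and 4 rose adjusted over the list alone). That list's adjusted p was 0.28 with an estimated correlation.

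A further 6 lists passed camera as higher only with its preset correlation. They were nonlymphoid tissue Treg genes (Batf, Nfil3 and Ccr2 of 24 rose, 3 adjusted over the list alone, adjusted p = 0.052 with an estimated correlation), the cell cycle (0 of 39 passed, median log2 0.55, adjusted p = 0.31 with an estimated correlation), TNF receptor and NF-kB genes (4 of 30 rose and Tnfaip3 fell, 6 and 3 adjusted over the list alone, adjusted p = 0.24 with an estimated correlation) and glycolysis (1 of 27 rose, Pkm, and 9 rose and 1 fell adjusted over the list alone, adjusted p = 0.17 with an estimated correlation). The others were sterol synthesis (0 of 22 passed, median log2 0.47, adjusted p = 0.17 with an estimated correlation) and effector molecules (1 of 16 rose, 2 adjusted over the list alone, adjusted p = 0.13 with an estimated correlation). That effector gene was Gzma, which encodes granzyme A, with 1 count in the mock group and a ratio of 207 (95% counting interval 36.8 to 8187); it is also on the list of CD8 T and NK markers. By fry in one direction, these 6 lists were called except the cell cycle. The tissue residency list was called lower, with a median log2 of -0.01 and a mean of -0.43 (Nr4a3 and Bhlhe40 fell and Isg20 rose, 5 and 2 adjusted over the list alone, adjusted p = 0.24 with an estimated correlation). Chemokine receptors (2 of 30 rose and 2 fell, 6 and 4 adjusted over the list alone, fry adjusted p = 0.0052 in one direction) and follicular regulatory genes were not called by camera (adjusted p = 0.17 and 0.93).

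Transcripts of other cell types differed between the groups as well. Lyz2, a macrophage gene, had 176, 210 and 14.98 CPM in mock mice a, b and c and at most 1.64 CPM in infected nodes, and it was among the genes called lower. The 9 tested macrophage, monocyte and dendritic cell markers had a median log2 of -1.47 with infection. Their camera adjusted p was 0.059, with 2.8e-05 without mock mouse a and 0.93 without mock mouse b. The class II gene H2-Aa reached 196 CPM in mock mouse b and 2.56 CPM in mock mouse c, and the NK cell gene Klrb1c 20.9 CPM in mock mouse c and 0 CPM in the other mock mice. The 4 tested CD8 T and NK markers had a median log2 of 2.43 with infection (camera adjusted p = 0.052, from 0.027 without infected mouse g to 0.58 without mock mouse a; fry adjusted p = 0.0043 in one direction). All 7 measured markers of these cells summed to 50.9 ± 13.1 CPM in infected and 34.7 ± 20.1 CPM in mock nodes (exact permutation p = 0.34). Cd8a had 6.84, 10.5, 2.08 and 0 CPM in infected mice d to g and at most 0.54 CPM in mock nodes. Cd40lg and Bhlhe40, on the list of conventional CD4 effector genes, fell. The 5 measured B cell markers summed to 107 ± 21.8 CPM in infected nodes (n = 4) and 32.9 ± 0.713 CPM in mock nodes (n = 3, exact permutation p = 0.057, the smallest that 3 against 4 can give; 0.109 adjusted over 21 such tests). The marker genes with the highest levels on their lists, Epcam (45.0 ± 17.7 against 18.8 ± 8.85 CPM), Pecam1 (74.7 ± 10.7 against 104 ± 9.49 CPM), Mmp9 (12.7 ± 8.76 against 1.06 ± 1.72 CPM), Ctss (618 ± 104 against 623 ± 34.6 CPM), Cd79b (51.8 ± 11.2 against 22.1 ± 10.3 CPM) and Cd8b1 (31.2 ± 7.97 against 18.3 ± 7.57 CPM), did not pass. Counts of calls moved with single libraries. Without mock mouse c there were 150 higher and 75 lower genes, without mock a 60 and 20, and without mock b 42 and 14. Without infected mouse d there were 35 and 12, without e 47 and 29, without f 43 and 14, and without g 56 and 28.

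**Figure D2:**
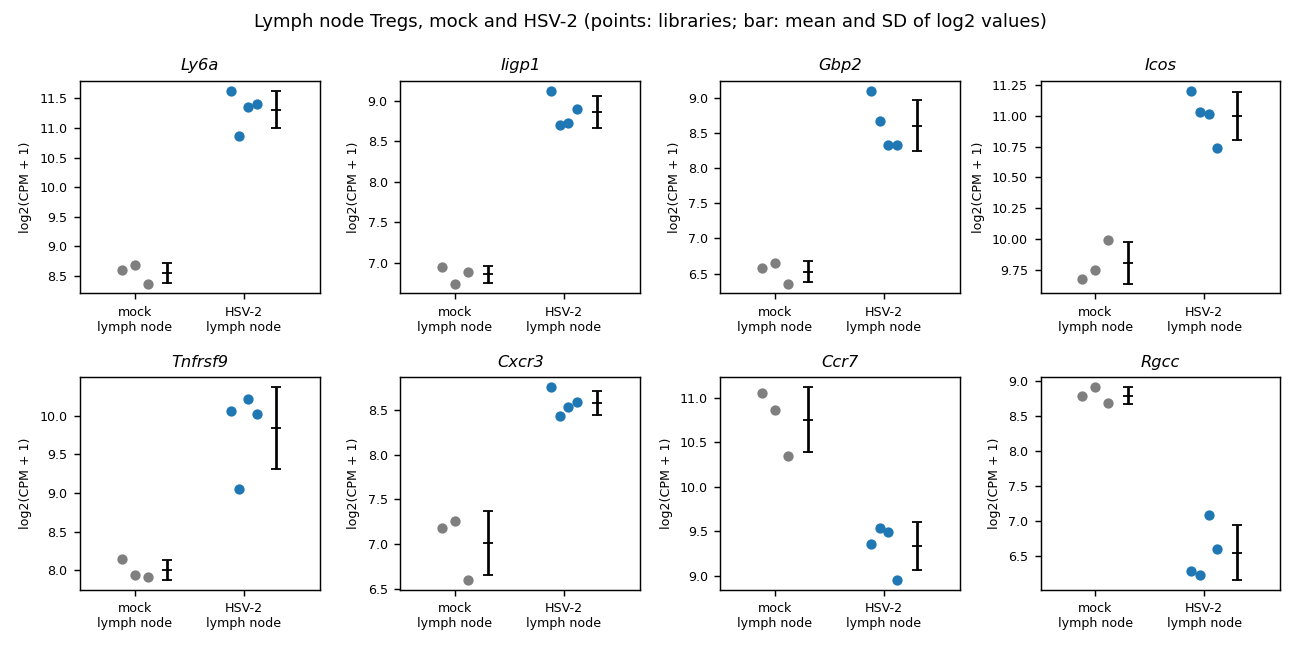
Expression of 8 genes in lymph node Tregs of mock (grey) and HSV-2 infected (blue) mice, on a log2(CPM + 1) axis. Each point is 1 library and the bar beside it the mean and SD of the log2 values; Ly6a, Iigp1, Gbp2, Icos, Tnfrsf9 and Cxcr3 lie higher and Ccr7 and Rgcc lower in every infected library.

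In infected mice, tissue Tregs expressed more Klrg1, Tbx21, Nkg7 and S100a6 than lymph node Tregs, and less Myc, Bcl2, Gpr83 and Ccr7, while none of 18 gene lists was called with an estimated correlation. These calls are from the fit without a block. With mouse as a block in edgeR, Klrg1, S100a6, Myc and Bcl2 stayed called. Tbx21, Nkg7, Gpr83 and Ccr7 did not (adjusted p = 0.091, 0.096, 0.065 and 0.091, edgeR). Klrg1, an inhibitory receptor of terminally differentiated lymphocytes (GRCm38 chromosome 6, 122270596 to 122282882, minus strand), was 5.89-fold higher in tissue (730 ± 122 against 124 ± 34.4 CPM, n = 4 each, log2 2.56, SE 0.21, adjusted p = 0.0010). Myc, a driver of growth and proliferation (chromosome 15, 61985391 to 61990374, plus strand), fell by 2.63 on the log2 scale (SE 0.22, adjusted p = 0.0010), from 143 ± 15.7 to 23.1 ± 5.25 CPM. In the main test without a block, 41 of 10424 tested genes were higher in tissue and 13 were lower. Over all tested genes, the groups' libraries did not overlap in 8.14%, where chance gives 2.86%.

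Of 17 Th1-type genes, 3 were higher in the fit without a block (8 adjusted over the list alone). None of the 3 was called with mouse as a block in edgeR. They were Tbx21, which encodes the Th1 transcription factor T-bet (72.1 ± 17.4 against 18.4 ± 5.87 CPM, log2 1.97, SE 0.31, adjusted p = 0.030), the interferon-gamma receptor gene Ifngr1 (1624 ± 281 against 854 ± 150 CPM) and Nkg7, a gene of cytotoxic granules (597 ± 177 against 225 ± 65.8 CPM, log2 1.41, SE 0.26, adjusted p = 0.047). Of 24 activation genes, Klrg1 and the ectonucleotidase gene Entpd1, which encodes CD39 (227 ± 45.5 against 89.9 ± 14.6 CPM), were higher (9 higher and 1 lower adjusted over the list alone). Of 24 nonlymphoid tissue Treg genes, Klrg1 and the chemokine receptor gene Ccr2 (577 ± 178 against 221 ± 43.0 CPM) were higher (6 adjusted over the list alone). The other genes with the largest rise were the adaptor gene Lat2 (6.99-fold), Plac8 (4.29-fold), S100a6 (1252 ± 207 against 443 ± 121 CPM), Crip1 (2.67-fold) and the galectin gene Lgals1 (2.67-fold). Among 20 tissue residency genes, 1 was higher (Crem, 484 ± 48.1 against 271 ± 26.7 CPM; 3 higher and 1 lower adjusted over the list alone), and among 38 immediate-early and stress genes 1 was higher (Zfp36; 5 higher and 5 lower adjusted over the list alone).

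Of 22 recirculation genes, Ccr7 (221 ± 84.7 against 627 ± 112 CPM) and Il6ra (16.7 ± 3.70 against 51.7 ± 5.36 CPM) were lower (3 adjusted over the list alone). The survival gene Bcl2 fell from 124 ± 34.5 to 24.9 ± 3.73 CPM (log2 -2.31, SE 0.26, adjusted p = 0.0066). The orphan receptor gene Gpr83, on the Treg identity list, fell from 187 ± 56.1 to 22.5 ± 9.47 CPM (log2 -3.05, SE 0.35, adjusted p = 0.0066). Dtx1, Tubb2a, Itm2a and Cd96 were the other lower genes with the largest folds, and Ltb, which encodes lymphotoxin beta, was the member of the TNF receptor and NF-kB list that fell. Il2ra (775 ± 143 against 806 ± 163 CPM), Ctla4 (2440 ± 208 against 1758 ± 231 CPM), Cd4 and Ikzf2 did not pass; Ctla4 passed with DESeq2 and with limma-voom and quality weights. None of 54 interferon-stimulated genes passed, over all genes or adjusted over the list alone, with a median log2 of -0.15 (edgeR; 997 of all tested genes had an unadjusted p under 0.05).

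By camera with its preset correlation, 11 of 18 lists were called, and none of them with an estimated correlation. The activation, Th1-type and nonlymphoid tissue lists were called higher and the recirculation and follicular regulatory lists lower, each with an adjusted p = 0.089 with an estimated correlation. Of 9 follicular regulatory genes none passed, and 4 fell and 1 rose adjusted over the list alone. Glycolysis (0 of 25 passed, median log2 0.47, adjusted p = 0.17 with an estimated correlation), effector molecules (0 of 16 passed, 3 rose adjusted over the list alone, adjusted p = 0.28 with an estimated correlation), tissue residency (adjusted p = 0.39 with an estimated correlation), chemokine receptors (1 of 30 rose and Ccr7 fell, 7 and 3 adjusted over the list alone) and the cell cycle (0 of 39 passed; both adjusted p = 0.41 with an estimated correlation) were called higher. Sterol synthesis (0 of 22 passed, median log2 -0.25, adjusted p = 0.41 with an estimated correlation) was called lower. Interferon-stimulated (camera adjusted p = 0.068), immediate-early (0.94), TNF receptor and NF-kB (0.94), class I (0.29) and Treg identity lists (0.47, median log2 0.08 and mean -0.21, 3 of 12 higher and 3 lower adjusted over the list alone) were not called.

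Both tissues came from the same 4 mice. With mouse as a block in edgeR, 5 genes were higher (Klrg1, Plac8, S100a6, S100a4 and Glrx) and 3 lower (Myc, Bcl2 and Tubb2a). The other 17 named genes that had passed then had adjusted p from 0.0556 to 0.212, with log2 fold changes that moved by at most 0.105. Their standard errors had a median ratio of 0.944 to those without the block. The block left 3 residual degrees of freedom in place of 6. In limma-voom the block gave 63 higher and 21 lower genes. Scaling by library totals alone gave 17 higher and 12 lower genes. Without the tissue library of mouse d there were 59 higher and 28 lower genes. Without tissue e, f or g there were 16, 6 and 5 higher and 9, 6 and 8 lower, and without the lymph node of d, e, f or g 6, 5, 2 and 23 higher and 5, 5, 5 and 10 lower. The marker genes with the highest levels on their lists did not pass: Cd79b, Epcam, Pecam1, Ctss and Bhlhe40 differed by at most 0.45 on the log2 scale, Mmp9 had 38.3 ± 16.4 against 12.2 ± 8.30 CPM (exact permutation p = 0.029, the smallest that 4 against 4 can give; 0.109 adjusted over 21 such tests), and Gzma 63.6 ± 90.3 against 11.5 ± 7.41 CPM, of which the tissue library of mouse e had 202 CPM. The 5 B cell markers summed to 54.7 ± 16.5 CPM in tissue and 107 ± 21.8 CPM in lymph node, and the 12 macrophage, monocyte and dendritic cell markers to 870 ± 95.1 and 1270 ± 213 CPM (exact permutation p = 0.057 each, 0.109 adjusted).

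**Figure D3:**
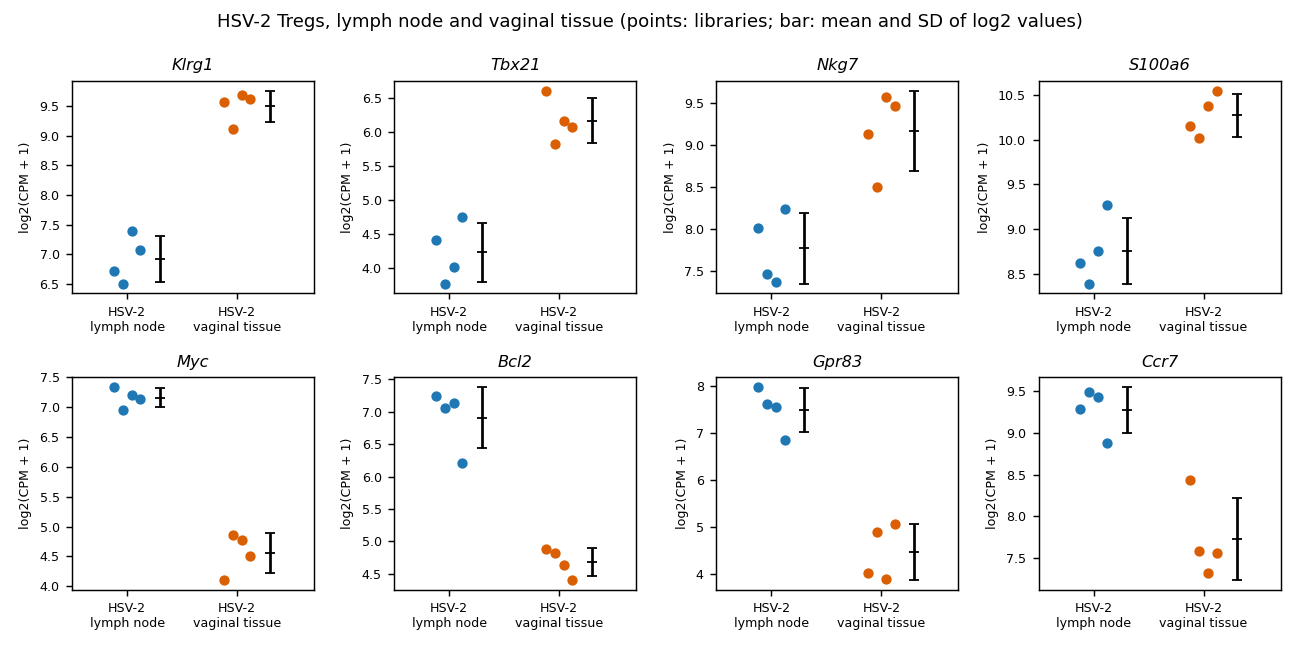
Expression of 8 genes in Tregs of infected mice from lymph node (blue) and vaginal tissue (orange), on a log2(CPM + 1) axis. Each point is 1 library and the bar beside it the mean and SD of the log2 values; Klrg1, Tbx21, Nkg7 and S100a6 lie higher and Myc, Bcl2, Gpr83 and Ccr7 lower in every tissue library.

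Infected tissue against mock lymph node, where tissue and infection change together, gave the most calls, 202 higher and 98 lower of 10586 genes. Activation genes (11 of 24 rose and Cd83 fell, 15 and 1 adjusted over the list alone), interferon-stimulated genes (20 of 54 rose, 26 adjusted over the list alone), glycolysis genes (10 of 25 rose and Pdk1 fell, 15 and 1 adjusted over the list alone) and class I presentation genes (5 of 16 rose, 11 adjusted over the list alone) were higher. Recirculation genes (6 of 23 fell and 2 rose, 12 and 2 adjusted over the list alone) were lower. These 5 lists kept their camera calls, with adjusted p of 0.017, 0.029, 0.043, 0.017 and 0.017 with an estimated correlation. So did the Th1-type (3 of 16 rose, 6 adjusted over the list alone, adjusted p = 0.017), nonlymphoid tissue (5 of 24 rose, 9 rose and 1 fell adjusted over the list alone, adjusted p = 0.023) and effector lists (Gzma and Gzmb rose of 15, 4 adjusted over the list alone, adjusted p = 0.043). Pkm, Ldha, Pgam1 and Gapdh, enzymes of glycolysis, were among the genes that rose. The metallothionein gene Mt1, whose product binds zinc and copper, had 156 ± 137 CPM in tissue and 2.16 ± 0.797 CPM in mock nodes (log2 6.12, SE 0.77, adjusted p = 0.0044). Mt2 had 1 count in the mock group and a ratio of 660 (95% counting interval 118 to 26103). Ifitm1, Muc20 and Cep112 had 0 counts in the mock group and were 342-fold, 127-fold and 131-fold higher when set against 3 counts over the group. Atp1b1 and Nmnat3 had 0 counts in tissue and were 248-fold and 165-fold lower by the same rule. These folds cover counting error and leave out the spread between mice. Tcf7, a transcription factor of naive and memory T cells, went from 214 ± 24.5 to 13.8 ± 8.67 CPM, Bcl2 from 287 ± 49.1 to 25.1 ± 3.75 CPM, and Nsg2 from 64.3 ± 18.0 to 4.71 ± 1.44 CPM. Il2ra (782 ± 145 against 383 ± 68.7 CPM) and Ctla4 (2462 ± 213 against 1376 ± 75.4 CPM) passed, while Cd4 and Ikzf2 did not.

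A further 6 lists were called by camera in this comparison with the preset correlation and not with an estimated one. Fry in one direction called Treg identity (adjusted p = 0.024) and the cell cycle (0.049) of these 6. Treg identity (3 of 12 rose and Gpr83 fell, 5 and 1 adjusted over the list alone, adjusted p = 0.17 with an estimated correlation), chemokine receptors (5 of 30 rose and Ccr7 fell, 9 and 4 adjusted over the list alone, adjusted p = 0.32 with an estimated correlation), the cell cycle (1 of 39 rose, Tk1, and 14 adjusted over the list alone, adjusted p = 0.17 with an estimated correlation) and TNF receptor and NF-kB genes (5 of 30 rose and Ltb fell, 6 and 5 adjusted over the list alone, adjusted p = 0.52 with an estimated correlation) were higher. Immediate-early genes (4 of 39 fell and Egr1 rose, 7 and 1 adjusted over the list alone, adjusted p = 0.25 with an estimated correlation) and the macrophage, monocyte and dendritic cell markers (Lyz2 fell of 10, 3 fell adjusted over the list alone, adjusted p = 0.24 with an estimated correlation) were lower. Lyz2 had 0 counts in tissue. Follicular regulatory (camera adjusted p = 0.060, fry 0.013 in one direction), sterol synthesis (0.51) and tissue residency lists (0.82, median log2 0.22 and mean -0.18) were not called by camera. Scaling by library totals alone gave 154 higher and 123 lower genes and a median log2 over all genes of -0.16 in place of -0.05. Without mock a there were 92 higher and 33 lower genes, without mock b 71 and 26, and without tissue e, f or g 115, 92 and 103 higher and 54, 40 and 56 lower.

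**Figure D4:**
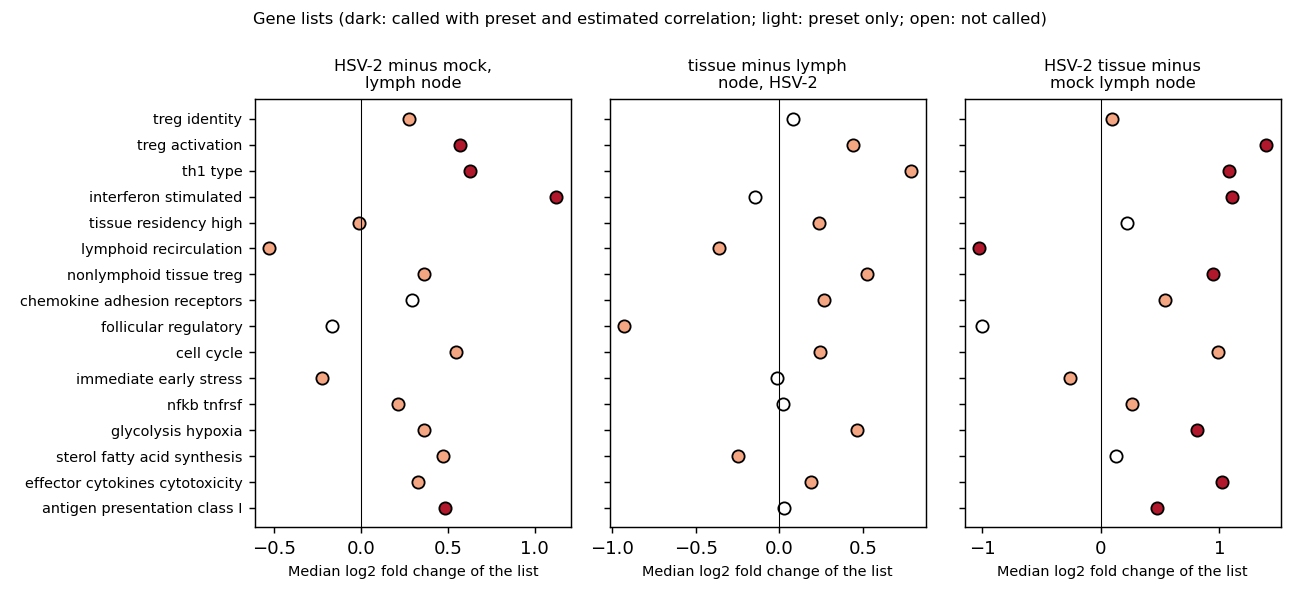
Median log2 fold change of each of 16 gene lists in the 3 comparisons, 1 point per list. Dark points are lists called by camera with both the preset and the estimated correlation, light points lists called with the preset correlation only, and open points lists not called; the interferon-stimulated list has a median of 1.13 with infection in the node and of -0.15 between tissue and node.

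Genes called in both main comparisons moved the same way. Of 10310 genes tested in both, 5 were higher with infection in the node and higher again in tissue (Glrx, AW112010, Tmem254a, S100a6 and Ccr2), and 5 were lower in both (Ccr7, Itm2a, Cd96, Bcl2 and Evl). None moved in opposite directions. Ccr2 lost its call in 9 of 17 alternatives with infection in the node and in 12 of 24 between tissue and node. A mouse block in the tissue comparison was an alternative added after the data were seen. With that block in edgeR, Glrx, S100a6 and Bcl2 were called in both and the other 7 were not. Independent lists of these sizes would share 0.333 higher and 0.0681 lower genes, and 0.111 and 0.204 in the 2 opposite combinations. Because the infected lymph node libraries enter both comparisons with opposite signs, chance alone gives a negative relation across genes. The correlation of the log2 fold changes was -0.081 where 40 simulations with no effect and the same shared libraries gave -0.46, and the covariance was -0.0588 where they gave -0.267, a difference of 0.209. The simulations gave all groups the same spread per gene. The shared infected node libraries varied least, with a mean correlation within their group of 0.885, against 0.804 in mock nodes and 0.822 in tissue. The simulated values may therefore be too negative, and the difference does not measure a shared effect. With the infected lymph node libraries divided so that none was shared, the correlation lay between 0.019 and 0.112 over the 6 ways to do so. No gene was called in both there, where at most 7 higher and 4 lower genes were called between tissue and node. The correlations are across genes, which are not independent replicates. Without the lymph node library of mouse d, e or f, 1 gene was called in both in the same direction, and without that of mouse g 3. Without mock a or b the number was 5 and 4, and without tissue f or g 3 and 4; without tissue f and without mock c, 1 gene was called in opposite directions.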

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

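The tests of depth, of the whole mouse, of CD8 T and NK cells, of the deviating library, of handling and of thinning, and the counts over other splits, were chosen after the results they bear on were seen; the tests of zeros by expression level, of mock mouse c and of interferon-stimulated genes by library were set before theirs, except that reading the zeros test against a counting interval, and the conditions under which the tests of mock mouse c and of interferon-stimulated genes can decide, were added after their values were seen. The test of CD8 T and NK cells was run on 3 sets of genes, of which the last, without genes of the Treg and T cell lists, is given. Of 133 values looked at in groups of 4 libraries, 9 had 1 library far from the other 3, where chance gives about 1 in 20.

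The tissue library of mouse d lay far from the other tissue libraries on the first principal component (193, the others at most 6.28) and on the second (27.6, the others at most -45.6). Lower depth is argued against, since at equal totals it still held 9392 genes, a distance from the mean of the others of -7.46 of their SDs. A difference of the whole mouse is argued against by a correlation of -0.000492 between the deviations of its 2 libraries, inside the range of -0.085 to 0.069 between different mice. Few captured molecules stay open. Genes at 0 fell 41.6-fold, from 21.4% at 10 to 20 CPM to 0.513% at 50 to 100 CPM, as such a cause needs. They also fell in the tissue of mice e, f and g, from 2.76, 1.34 and 2.46% to 0%, so this fall cannot point to the cause. Of genes of at least 20 CPM, 8.89% lay over 4-fold below the other libraries, against 1.56, 0.621 and 1.33% in mice e, f and g. Over 4-fold above the other libraries lay 5 of 6414 genes. The bound set beforehand against this cause, no more such genes than in the other tissue libraries, was met, since 1 of those had 6; it was left undecided because the exact 95% interval of the 5 genes, 1.62 to 11.7, includes 6, an interval brought in only after the bound had been met, and no biological explanation was tested.

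The Th1-type genes higher in tissue, Tbx21, Ifngr1 and Nkg7, lost their calls with mouse as a block in edgeR. With a mouse block in limma-voom, 2 of all named genes of this comparison lost theirs, and with a random block in limma 1. Not all of the Th1-type genes therefore lost their calls there. For the called genes as a set, the deviating library of mouse d is argued against as the cause, since 52 of the 54 were called without it. That count does not give Tbx21, Ifngr1 and Nkg7 separately. CD8 T or NK cells in the sort stay open. The 5 measured genes of these cells that are on no Treg or T cell list summed to 36.7 CPM in tissue and 38.2 CPM in lymph node. That was a change of -0.398% of the rise of Nkg7 (95% interval -5.43 to 4.63%) and of -0.193% of that of Ifngr1 (-2.63 to 2.25%), which met the bound set against this cause. For Tbx21, whose rise was smaller, the bound was not met (-2.75%, -37.5 to 32.0%). Cd8b1 made up most of the sum (25.6, 39.4, 36.0 and 29.9 CPM in the tissue of mice d to g), so the sum says little about NK cells. Cd8a had 0.178 against 4.88 CPM and Klrb1c 0 CPM in the 4 tissue libraries. Klrd1 had 0, 6.08, 2.26 and 2.68 CPM in tissue and 0.646, 1.91, 0.695 and 1.80 CPM in lymph node. The shares also depend on how strongly such cells express these genes relative to Nkg7 and Ifngr1, which was not tested. With Eomes and Gzma, which are on Treg or T cell lists too, the sum changed by -2.59, 1.23 and 0.865% of the rise of Nkg7 in the tissue of mice d, f and g and by 143% in that of mouse e, through Gzma. Digestion and handling of tissue cannot be told apart from location, since all tissue libraries and no lymph node library had them; immediate-early and stress genes had a median log2 of -0.014, and the intravascular antibody gate and the tissue itself stay open as well.

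For the genes changed with infection in the lymph node, lower depth in mock libraries is argued against, since 142 of 145 calls were kept after thinning to equal totals. Other cells in the mock libraries stay open: 75 genes called lower without mock mouse c differed from infected nodes in mock c by 64.5% of their difference in a and b, which met the bound set beforehand against this cause, but that bound took mock c as poor in such cells from Lyz2, and mock c had the highest Fcer1g (24.1 CPM) and Tyrobp (43.0 CPM) of the mock libraries. B cells in infected libraries stay open as well. The lowest of the 4 library medians over 22 interferon-stimulated genes was 74.0% of the highest (1.06 to 1.44), which met the bound set beforehand. The 22 genes were those called higher over these same libraries, which favours an even rise. That bound also needs a varying B cell content. Cd79a ran from 0.137 to 18.8 CPM, while the 5 B cell markers together ran only from 75.1 to 122 CPM, and a row that pools antibody gene segments (abParts) rose with infection from 1110 ± 173 to 3190 ± 357 CPM. An effect of infection stays open beside these and beside CD8 T or NK cells. The 4 tested genes of CD8 T and NK cells had a median log2 of 2.43, while all 7 measured markers summed to 50.9 against 34.7 CPM (exact permutation p = 0.34). Whether more cells or each cell changed is not separable in sorted pools.

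Other splits of the libraries into groups of the same sizes argue against chance for the counts of called genes with infection in the node (145 genes, highest of the others 0, 1 of 35 splits as large). They do so as well between infected tissue and mock node (300 genes, highest of the others 0, 1 of 35). A share of 1 in 35 is the smallest that these splits can give. For called lists, chance is not excluded with infection in the node (14 lists, highest other split 13, 1 of 35) or between infected tissue and mock node (14 lists, highest other 14, 2 of 35). With infection in the node the real split led narrowly, and only 4 of its 14 lists were called with an estimated correlation. Between tissue and node the libraries are paired by mouse, and the 8 splits that part the libraries of all 4 mice are too few for a share under 1 in 20 (54 genes for the real one and at most 0 for the others, 11 lists and at most 7). Over all 35 splits, which leave the pairing aside, 1 reached 54 genes and 2 reached 11 lists (highest other 0 genes and 11 lists).

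Single values far from the rest of their group were Ctla4 in the lymph node of mouse g (1443 CPM, the others at least 1888), Nfil3 in the lymph node of mouse e (528 CPM, the others at most 444), Crem in the lymph node of mouse g (237 CPM, the others at least 285) and in the tissue of mouse e (568 CPM, the others at most 467), Gzma in the tissue of mouse e (203 CPM, the others at most 22.4), Il2ra in the tissue of mouse f (992 CPM, the others at most 734) and Mt2 in the tissue of mouse d (121 CPM, the others at most 24.1). These CPM use a scaling over all 11 libraries.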

How the results depend on the processing

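The block with limma, the settings that leave out mouse d or g from both tissues, the blocked list test with an estimated correlation and, in the overlap, leaving out libraries and the mouse block were chosen after the data were seen. No named gene that passed changed direction under any alternative, and 18 of 42 with infection in the node, 3 of 23 between tissue and node (Bcl2, Klrg1 and Myc) and 4 of 12 between infected tissue and mock node passed under all of them. The kept direction says little, since the groups' libraries did not overlap in any called gene (145, 54 and 300 genes). Where a value moved, the cause was not tested. Simulated 2-fold changes were recovered in 15%, 14% and 4% of genes in the 3 comparisons.

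With infection in the node, DESeq2 called 343 higher and 198 lower genes, and a fit of all 11 libraries 35 lower. Leaving out single libraries gave 35 to 150 higher and 12 to 75 lower genes and 14 to 15 lists, and an estimated correlation 4 lists. Ccr2, Isg20, Lamc1 and Hspa1a lost their call in 9 of 17 alternatives and Gzma in 9 of 16. Cnn3 and Rgs16 lost theirs in 8 of 17, and Nr4a3, Scml4 and Ttn in 7 of 17. Ikzf2, which did not pass, had a log2 of 0.0202 with quality weights and -0.175 to 0.162 without single libraries, and Ctss -0.136 to 0.0443.

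Between tissue and node, 23 higher genes also reached 2-fold, library totals alone gave 17 higher, DESeq2 188 higher and 127 lower, limma-voom 20 lower, quality weights 116 and 49, and all 11 libraries 21 higher. The mouse block gave 5 higher and 3 lower. Mouse as a random replicate block in limma (consensus correlation 0.0354) gave 63 and 21, and limma-voom with the block also 63 and 21. The block without mouse d gave 21 higher, no mouse d in either tissue 12 higher, and no mouse g 12 and 6. Single libraries left out gave 2 to 59 higher and 5 to 28 lower genes and 8 to 14 lists; an estimated correlation called 0 lists with or without the block, and fry in one direction 5. The block ended no list call with the preset correlation. Ctla4, with an adjusted p of 0.15, passed with DESeq2 (0.0055) and quality weights (0.028) and reached 0.34 over its alternatives. Of other genes that did not pass, Epcam had a log2 of -0.0307 with totals alone, -0.0528 with the block and -0.0464 without mouse g; Bhlhe40 0.00528 with quality weights, 0.00459 with the block and 0.28 without mouse g; and Pecam1 0.13 with quality weights, 0.0185 thinned, and 0.23 with and 0.24 without the block when mouse d was left out, where Cd79b had 0.0761 and 0.0820 and Il2ra 0.0567 and 0.0585. Without single libraries, Cd79b ran from -0.190 to 0.0474, Il2ra from -0.196 to 0.0329, Pecam1 from -0.244 to 0.168, Epcam from -0.236 to 0.366, Ikzf2 from -0.0424 to 0.518 and Bhlhe40 from -0.145 to 0.186.

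Between infected tissue and mock node, DESeq2 gave 516 higher and 318 lower genes, quality weights 308 and 221 and all 11 libraries 369 and 183. Single libraries left out gave 71 to 230 higher and 26 to 117 lower genes, 11 to 15 lists, and -0.0660 to 0.493 for Ikzf2; an estimated correlation called 8 lists. The correlation of the main comparisons was -0.0480 by Spearman, -0.0276 with a stricter filter and -0.196 to -0.0285 without single libraries, where 1 to 14 genes were called in both. With the mouse block it was -0.0906, with 3 genes called in both. With divided lymph node libraries it was 0.0192, 0.0596, 0.104, 0.0259, 0.0644 and 0.112, with 0 genes called in both (edgeR; no other tool was run on these divisions).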

Other observations

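Several gene groups outside the fixed lists were chosen after their values were seen and are given as values. In tissue, S100a4, S100a10 and S100a11, which encode small calcium-binding proteins, and Vim, which encodes vimentin, were called higher than in the infected lymph node along with S100a6, Crip1 and Lgals1. Of these genes, only S100a4 and S100a6 were called with mouse as a block in edgeR. S100a10 had 2098 ± 292 against 1032 ± 224 CPM (SD, n = 4 each), S100a11 707 ± 96.7 against 328 ± 69.2 CPM, S100a4 619 ± 147 against 239 ± 84.2 CPM and Vim 894 ± 71.0 against 339 ± 114 CPM. With infection in the node, S100a4, S100a10, S100a11 and Vim did not pass (adjusted p of 0.364, 0.268, 0.642 and 0.957, edgeR). Gzmb, which encodes granzyme B, had 1302 ± 631 CPM in infected and 59.3 ± 93.0 CPM in mock nodes (adjusted p = 0.11) and 2787 ± 1298 CPM in tissue, and passed in infected tissue against the mock node (adjusted p = 0.046).

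Mt1 had 2.21 ± 0.816 CPM in mock nodes and 25.4 ± 12.8 CPM in infected nodes (adjusted p = 0.052, edgeR), and 155 ± 136 against 24.3 ± 12.2 CPM between tissue and infected node (adjusted p = 0.11), so that only the comparison of infected tissue with the mock node passed. Hspa1a had 79.4 ± 43.6 CPM in infected nodes, 9.25 ± 3.98 CPM in mock nodes and 9.96 ± 11.7 CPM in tissue, and Hspa1b 145 ± 61.3, 29.9 ± 19.5 and 18.7 ± 12.6 CPM; of these differences only Hspa1a with infection in the node passed. A row that pools antibody gene segments (abParts) rose with infection in the node, from 1110 ± 173 to 3190 ± 357 CPM (log2 1.52, SE 0.14, adjusted p = 0.0010), and had 2943 ± 680 CPM in tissue.

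A hypothesis formed, with its test, after the shared calls were seen is that infected lymph node Tregs lie part of the way from mock node Tregs towards tissue Tregs. It needs a positive relation across genes between the effect of infection and that of location once no library is shared. The 6 ways to divide the infected lymph node libraries reuse the same libraries, so they are not separate tests, and no spread without an effect was computed for them. The correlation was above 0 in 6 of 6 ways, with a lowest value of 0.019 and a highest of 0.112, and the covariance ran from 0.0207 to 0.131. This is consistent with the hypothesis for a small part of the variation, and it may also come from a shared state of the 4 infected mice, since both tissues were taken from them.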
